A study of Caenorhabditis elegans with 2 samples.

How the data were processed

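Binding of FKH-10, a forkhead-family transcription factor, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole first-larval-stage (L1) Caenorhabditis elegans of mixed sex. The animals carried an integrated fkh-10 transgene whose product had a C-terminal GFP and FLAG tag, with unc-119 as the transformation marker. The samples formed 1 group of 2 biological replicates, numbered as in the labels, and no second condition was included. Chromatin was fragmented by sonication, per the labels, and the replicates came from separate biosamples. The labels name a possible control experiment, whose values were not analysed here. The antibody is labelled only with the name of the target.

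For each of the genome builds ce10 and ce11 the authors deposited a peak list per replicate, a relaxed list called on the pooled replicates and an optimal set thresholded by irreproducible discovery rate (IDR). Each list is in narrowPeak format. Per the text files deposited with each sample, the lists derive from the alignments and a control file. The deposited signal value per peak was never negative and its scale is not given, so it was used here to rank, filter and describe peaks within a list. The deposited q-value column holds −log10 q and is capped: 1868 of the 2602 optimal peaks share the top value, so it served only as an alternative rank. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. All 2602 optimal ce11 peaks were listed with the same interval, summit and signal in the pooled list, and they were the 2602 pooled peaks with the highest signal. The optimal set therefore acts as a cut on the pooled signal at 37.0, and the other 17322 pooled peaks lie below it. Read depth is unknown, because the lists hold no read counts, and no interval that needs depth is given. The binomial intervals below cover the sampling of peaks or genes only.

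Positions are 1-based on ce11. Genes were taken from Ensembl release 115 (WBcel235, the same coordinates as ce11), and summit sequences from the RefSeq copy of that assembly, whose chromosome lengths hold every listed peak. Coordinates were not converted between builds. A promoter window ran from 1000 bp upstream to 200 bp downstream of the annotated start of a protein-coding gene, and 19973 such genes lie on chromosomes I to V and X. The summits in 286 of the promoter peaks fell in the windows of 2 or more genes, and each such gene was counted.

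Replicates were compared by the overlap (at least 1 bp) of their 2602 highest-signal peaks and by Spearman's rho over summits paired within 100 bp, with 1000 bootstrap resamples of the pairs. Promoter shares, replicate overlap and non-coding RNA genes (within 500 bp of a summit) were tested against 1000 seeded random placements within chromosomes, 2-sided, for which 0.002 is the smallest p possible. Peaks per chromosome were tested by exact binomial tests, and 35 gene lists by 2-sided Fisher's exact tests against all other protein-coding genes. For 8 sequence words, windows reaching 50 bp to each side of the summit were compared with windows centred 300 bp to a seeded side by exact McNemar tests; ratios had 0.5 added to each count. The Benjamini-Hochberg adjustment was made within each family with a threshold of 0.05. Intervals are exact 95% binomial (Clopper-Pearson). Peaks near each other, genes in operons or clusters and genes with a shared divergent promoter are not independent, so these p-values describe these peak lists and are not tests between conditions.

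The lists, words, tests, alternatives and the rule for named items were fixed before the data were examined. The named items are fkh-10 and unc-119; the 20 optimal peaks with the highest signal; in each called gene list the members with the 3 highest-signal promoter peaks; in every other list the member with the highest; all forkhead-family genes with a promoter peak; and the 5 optimal peaks whose ranks differ most between replicates. The peak of highest signal in the chemoreceptor list is not reported here. The alternatives covered other overlap rules, peak numbers, ranks and pairing distances, the ce10 lists, the higher-signal 1301 optimal peaks, the top peaks of each replicate alone, optimal peaks found in the top peaks of both replicates, removal of peaks near fkh-10 and unc-119, other promoter windows and gene assignments, a logistic regression with upstream length, and other forkhead words, windows and controls. No symbol of the annotation matched ift-140, tmem-216, elt-5, exc-2, exc-3, etf-1, etf-3, vars-2, atp-6, phi-6 or daf-21, which were left out of their lists.

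The code was tested on simulated data. For the gene lists, 5 of 5 planted lists and 0 of 15 unplanted lists were called. For the promoter share a first run with 1 random set gave a p under the threshold, after which 40 sets were drawn; 2 of 40 sets of 2602 random summits had a p under 0.05, and planted promoter summits making up 52.6% were recovered as 52.6%. For the forkhead word, sites planted to give 23.6% of 2602 windows were recovered as 23.5%. The simulated summit and flank windows had the same base composition, unlike the real ones, so the effect of composition was not tested there. For the replicates, 60.4% of peaks planted as shared gave an overlap of 61.4%, and 1572 planted pairs of summits gave 1575 pairs. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6 were used.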

Results

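FKH-10 ChIP-seq in whole L1 larvae gave 28842 peaks in replicate 1 and 28896 in replicate 2. The pooled list held 19924 peaks and the optimal set 2602, on ce11. Optimal peaks had a median width of 376 bp and a median signal of 60.7, with a range from 37.0 to 457. Read depth is unknown. The signal is the authors' value per peak and carries no error of its own, so the signals of both replicates are given for the leading peaks.

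The first question was how far the replicates found the same sites. Of the 2602 highest-signal peaks of replicate 1, 1896 (72.9%, 95% interval 71.1 to 74.6%) overlapped a peak among the 2602 highest of replicate 2. In the other direction 1892 (72.7%) did. Random placement gave 2.01% on average (permutation p = 0.002, the smallest the placements can give). Placement was uniform within chromosomes and does not account for the concentration of peaks in promoters, so this p does not measure how reproducible FKH-10 sites are. Of the optimal peaks, 1873 (72.0%, interval 70.2 to 73.7%) overlapped the top peaks of both replicates, 312 those of replicate 1 alone, 369 those of replicate 2 alone and 48 those of neither. Across 6597 paired summits the signals of the replicates had a Spearman rho of 0.712 (bootstrap interval 0.699 to 0.727); these are peaks, which are not independent replicates. When all peaks of each list were used, the overlap was 40.9% against 20.2% by random placement. The 5 optimal peaks whose replicate ranks differed most lay in introns of pde-4, glb-32 and F20G2.6, in the shared promoter of cyb-1 and orc-5, and between genes near F55A4.3. The pde-4 peak (chromosome II, 7639653 to 7640028) ranked 27936 in replicate 1, with a signal of 7.70, and 1362 in replicate 2, with a signal of 28.4. The F55A4.3 peak (chromosome X, 1022032 to 1022407) had the opposite order, with rank 809 and a signal of 42.7 in replicate 1 and rank 23726 and a signal of 5.24 in replicate 2.

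Optimal summits were concentrated in promoters and rare in coding exons outside promoter windows. Each summit had a single class, and promoter windows took precedence over exons, introns and intergenic sequence. In all, 1000 summits (38.4%, interval 36.6 to 40.3%) lay in a promoter window, against 20.9% by random placement (permutation p = 0.002). Coding exons held 54 summits (2.08% against 19.9% placed) and UTRs or other exons 44 (1.69% against 3.14%). Introns held 704 (27.1% against 30.7%) and intergenic sequence 800 (30.7% against 25.3%). The adjusted permutation p was 0.002 for each class. Pooled peaks below the optimal threshold were in promoters at 24.2%, against 21.3% placed (permutation p = 0.002).

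Ribosomal protein genes had a promoter peak more often than any other of the 35 lists, except that pan-neuronal genes exceeded them with the long promoter window (71.4% against 71.1%) and that both they and insulin and dauer signalling genes did with each summit given to the nearest gene start (89.3% and 40.6% against 38.6%). A promoter summit was found at 1275 of 19973 protein-coding genes (6.38%). Of the 83 ribosomal protein genes, 57 had a promoter peak (68.7%, interval 57.6 to 78.4%), against 6.12% of other genes (Fisher's exact test, adjusted exact p = 3.97e-47). The strongest of these peaks were at rpl-3, with a signal of 409, 265 bp upstream of the gene start, at rpl-20 with 290.2 and at rpl-12 with 277. Translation factor genes had peaks at 14 of 39 (35.9%, interval 21.2 to 52.8%, adjusted exact p = 3.38e-07). They included iff-2, the eIF5A homologue, with a signal of 218.4, and the elongation factor genes eef-1A.2 with 194 and eef-1A.1 with 127. The eef-1A.1 summit also lay beside the miRNA gene cel-mir-5549. Of the tRNA synthetase genes, 3 of 32 had a peak (9.38%, adjusted exact p = 0.628), the strongest at ears-2 with a signal of 91.1.

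Other genes of general cell function also had promoter peaks more often than the rest. Spliceosome genes had peaks at 18 of 47 (38.3%, interval 24.5 to 53.6%, adjusted exact p = 2.49e-09), led by snr-4, rsp-6 and prp-19 with signals of 77.5, 76.5 and 74.1. The snr-4 summit (chromosome V, 11980073), 350 bp from that gene start, also lay beside the snRNA gene T11F9.15 (11980118 to 11980261). Heat shock and chaperone genes had peaks at 16 of 42 (38.1%, interval 23.6 to 54.4%, adjusted exact p = 2.07e-08), led by the Hsp70 gene hsp-1 with a signal of 236, the chaperonin subunit gene cct-7 with 191 and the mitochondrial chaperonin gene hsp-60 with 181. Mitochondrial respiratory chain genes had peaks at 15 of 49 (30.6%, interval 18.3 to 45.4%, adjusted exact p = 1.10e-06), led by cox-5B with a signal of 200.2, cox-5A with 188 and atp-1 with 125. Vacuolar ATPase genes had peaks at 6 of 21 (28.6%, interval 11.3 to 52.2%, adjusted exact p = 0.00461), led by vha-12, vha-13 and vha-15 with signals of 102, 79.8 and 77.8. Proteasome genes had peaks at 9 of 33 (27.3%, interval 13.3 to 45.5%, adjusted exact p = 0.000571), led by rpn-3, rpn-11 and rpt-2 with signals of 116, 106 and 85.5. The proteasome call was lost in the higher-signal 1301 peaks (adjusted exact p = 0.0685) and in the peaks found in both replicates (adjusted exact p = 0.174). The vacuolar ATPase call was lost when each summit was given to the nearest gene start (adjusted exact p = 0.387).

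Among tissue lists, pan-neuronal genes stood apart. Of 28 genes used throughout the nervous system, 13 had a promoter peak (46.4%, interval 27.5 to 66.1%, adjusted exact p = 2.92e-08). The strongest were at unc-108, which encodes a Rab2 GTPase, with a signal of 183 and a summit 44 bp upstream of the gene start, at rgef-1 with 161 and at the synaptic vesicle gene rab-3 with 122. Genes that give a neuron its transmitter had a peak at 1 of 21, unc-25, with a signal of 62.9. With each summit given to the nearest gene start they had 6 of 21 and were called higher (adjusted exact p = 0.0379). Cilium genes of sensory neurons had peaks at 5 of 63 (7.94%, adjusted exact p = 0.750), the strongest at klp-11 with a signal of 105. Neuropeptide genes had peaks at 2 of 102 (1.96%, adjusted exact p = 0.146), the stronger at flp-22 with a signal of 93.7. They were called lower with the top peaks of replicate 2 alone (1 of 102, adjusted exact p = 0.0395) and with the short promoter window (0 of 102, adjusted exact p = 0.0270), and had 3 of 102 with those of replicate 1 alone. No promoter peak was found at any of 37 pharynx, 47 intestine, 42 epidermis and seam, 19 glia, 59 hedgehog-related and 6 Hox genes. By the rule of 3 over n, a count of 0 allows shares of up to 8.11%, 6.38%, 7.14%, 15.8%, 5.08% and 50% in these lists, and none of them passed the test (adjusted exact p from 0.0807 to 1). Body wall muscle genes had peaks at 4 of 35 (11.4%, adjusted exact p = 0.410; strongest at act-4, signal 53.1), and excretory system genes at 1 of 19, vha-8, with a signal of 64.2.

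The 4 lists called lower were chemoreceptor, C-type lectin, F-box and detoxification genes. Other families, among them nuclear hormone receptor, collagen, histone and major sperm protein genes, were not called in the main setting. Chemoreceptor genes had peaks at 5 of 1365 (0.366%, interval 0.119 to 0.853%, against 6.83% of other genes, adjusted exact p = 1.05e-31). The list was made by symbol pattern, and a peak at its member sri-5 had a signal of 85.2. C-type lectin genes had a peak at 1 of 240, clec-126, with a signal of 39.98 (adjusted exact p = 1.59e-05). That summit (chromosome II, 3519296) lay within a tRNA gene (3519250 to 3519322). F-box genes of the fbxa and fbxb families had peaks at 3 of 274, at fbxb-58, fbxb-85 and fbxa-90 with signals of 254, 134 and 108.4 (adjusted exact p = 0.000114; 0.112 in the higher-signal 1301 peaks). Detoxification genes had peaks at 2 of 185, at ugt-18 with a signal of 55.7 and gst-27 with 38.3 (adjusted exact p = 0.00240). The gst-27 summit was also within 500 bp of the snoRNA gene Y53F4B.48. Clustered genes are not independent of each other.

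**Figure D1:**
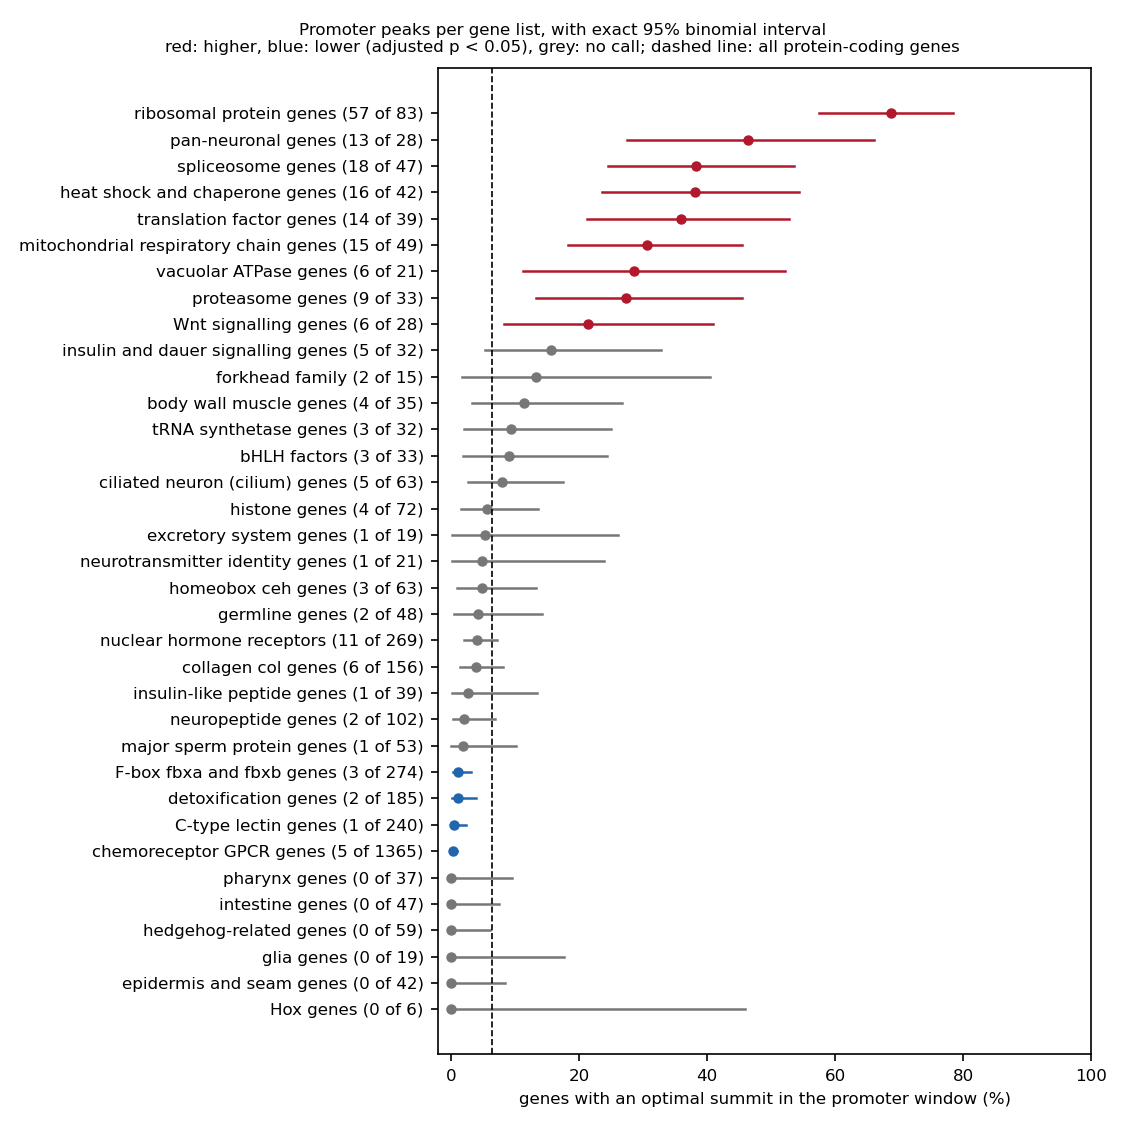
Share of genes (percent) with an optimal summit in the promoter window for each of 35 gene lists, with the count in brackets. Points are shares and lines exact 95% binomial intervals; ribosomal protein genes lie at 68.7% and the dashed line for all protein-coding genes at 6.38%.

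Wnt signalling genes had peaks at 6 of 28 (21.4%, interval 8.30 to 40.95%, adjusted exact p = 0.0201), led by the receptor gene lin-18 with a signal of 109.6, the ligand gene cwn-2 with 109 and the Dishevelled gene mig-5 with 104.3. This call was lost with the top peaks of replicate 1 alone (adjusted exact p = 0.0606), with those of replicate 2 alone (0.0789) and under 3 other alternatives. Of 15 forkhead-family genes, 2 had a promoter peak (13.3%, adjusted exact p = 0.394): daf-16, the FOXO gene, with a signal of 70.4 and fkh-9 with 55.6. Homeobox ceh genes had peaks at 3 of 63 (strongest at ceh-38, signal 104.3), nuclear hormone receptor genes at 11 of 269 (nhr-14, signal 115) and bHLH genes at 3 of 33 (mdl-1, signal 105). The adjusted exact p values of these lists lay between 0.243 and 0.901; nuclear hormone receptor genes were called lower with the long promoter window (adjusted exact p = 0.00852). Insulin and dauer signalling genes had peaks at 5 of 32 (15.6%, adjusted exact p = 0.118), the strongest at akt-2 with a signal of 79.0. Insulin-like peptide genes had a peak at 1 of 39, ins-39, with a signal of 300.05. Histone genes had peaks at 4 of 72 (his-37, signal 247), collagen genes at 6 of 156 (col-71, signal 84.9), germline genes at 2 of 48 (mex-1, signal 67.3) and major sperm protein genes at 1 of 53 (ssp-34, signal 58.1). None of these passed the test.

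The X chromosome held more optimal peaks than its length predicts, and chromosome V fewer. X had 644 peaks (24.8%, interval 23.1 to 26.5%) against 17.7% expected from length, a ratio of 1.40 (exact binomial test, adjusted exact p = 5.24e-19). V had 364 (13.99% against 20.9%, adjusted exact p = 5.24e-19) and IV 397 (15.3% against 17.4%, adjusted exact p = 0.00594). Chromosome I had 435 (16.7% against 15.03%, adjusted exact p = 0.0255), II had 375 and III 387 (adjusted exact p = 0.252 and 0.118). The calls on I and IV were lost in the higher-signal 1301 peaks (adjusted exact p = 0.0542 and 0.0690) and in the peaks found in both replicates (0.0628 and 0.0524), and II was called lower in the former (0.0301). Against the share of protein-coding genes, 13.7%, the ratio for X was 1.81, and II was called lower, III higher and IV not (adjusted exact p = 0.000178, 0.0166 and 0.112). In the subsets chosen after the data were seen, X held 58 of the 200 peaks with the highest signal (29.0%) and 14 of the 20 highest (70%, interval 45.7 to 88.1%).

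**Figure D2:**
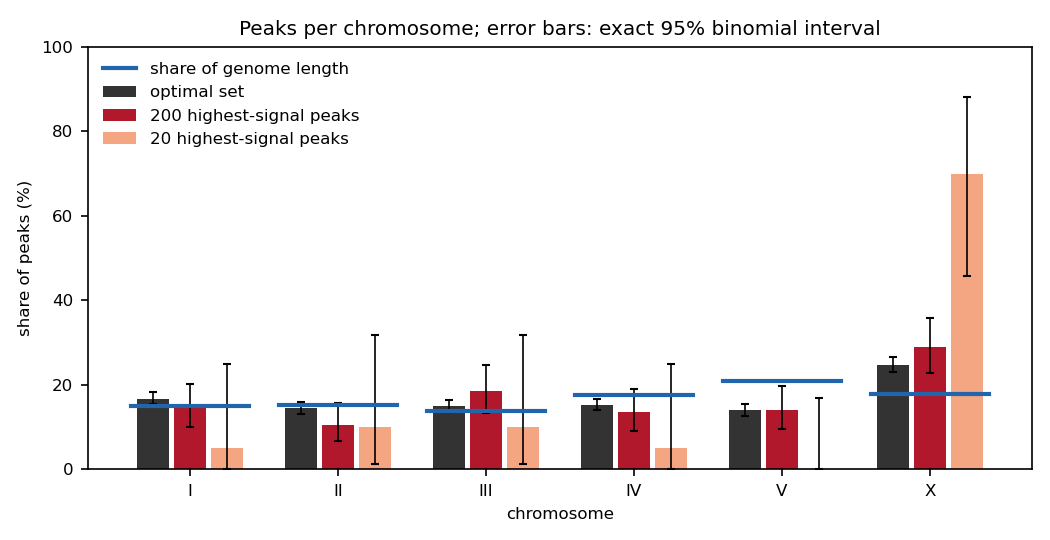
Share of peaks (percent) on each chromosome in the optimal set and among its 200 and 20 highest-signal peaks. Bars start at 0, error bars are exact 95% binomial intervals and blue lines give the share of genome length; X holds 70% of the 20 highest peaks and 17.7% of the length.

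Most of the 20 strongest peaks lay on X, and most of these outside the promoter windows of protein-coding genes. The highest signal, 457, was in an intergenic peak on X (11093946 to 11094397), 3955 bp from the nearest start of a protein-coding gene, W02H3.3, and 1442 bp from that of a tRNA gene; its signals were 252 in replicate 1 and 207 in replicate 2. The summit sequence from 11094216 to 11094246 reads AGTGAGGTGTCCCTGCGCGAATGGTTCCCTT. The third peak lay in an intron of mom-1, which acts in Wnt secretion (X, 6296314 to 6296791, signal 412; replicates 187 and 227). Its summit sequence, from 6296548 to 6296578, is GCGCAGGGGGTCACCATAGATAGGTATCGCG. Other intergenic X peaks had their nearest protein-coding gene starts at F22H10.2 (signal 396), K02D3.1 (369.7), ZK899.6 (359.7), F20B6.9 (347), F19H6.5 (316), gtr-1 (312), xol-1 (302), F55G7.5 (301) and T27A8.7 (297). The summit of the peak listed with xol-1, the switch gene of sex determination, lay 4972 bp from that gene start, 416 bp from the start of a tRNA gene and 333 bp from that of the non-coding RNA gene C18A11.13. For 8 of the 20 peaks, 6 of them on X, the closest start was that of a gene that is not protein-coding; genes of other types were looked up after the peaks were seen. A further X peak lay in an intron of Y41G9A.17 (331), and those in the promoters of nspc-17 (319) and ins-39 (300.05) had summits 718 and 606 bp upstream. The 6 autosomal peaks were all in promoters. They were at cdc-48.1, an AAA ATPase gene (II, 10563446 to 10563703, signal 429; replicates 219 and 209), rpl-3 (III, 3867444 to 3867706), the divergent pair tasp-1 and K01G5.10 (III, 365), egg-5 (I, 315), H41C03.3 (II, 303) and the pair rpl-20 and Y17G9B.5 (IV, 290.2). Each of the 20 peaks ranked within the first 29 of both replicate lists.

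Small non-coding RNA genes had summits nearby more often than random placement gave. Of 612 tRNA genes, 98 (16.01%, interval 13.2 to 19.2%) had an optimal summit within 500 bp, against 3.11% placed (adjusted permutation p = 0.00333). Most of these 98 genes lay on X, so this result and the X excess share peaks. The share of all tRNA genes on X was not counted. The shares were 49 of 346 for snoRNA genes (14.2% against 2.87%, adjusted permutation p = 0.00333) and 14 of 129 for snRNA genes (10.9% against 2.60%, adjusted permutation p = 0.00333). For miRNA genes the count was 18 of 261 (6.90% against 3.01%, adjusted permutation p = 0.0175), and the call was lost within 200 bp (adjusted permutation p = 1) and with the top peaks of replicate 1 alone (adjusted permutation p = 0.0699). None of 20 rRNA genes had a summit nearby. Tandem copies can share a summit.

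The forkhead word was less common at summits than beside them. RTAAAYA, the type of site that forkhead proteins bind, occurred within 50 bp of 131 of 2602 summits (5.03%) and in 290 of the flanks (11.1%), a ratio of 0.453 (exact McNemar test, adjusted exact p = 5.65e-15). The looser word RYMAAYA also occurred less often at summits (18.8% against 27.6%), while the stricter TGTTTAC did not differ detectably (42 against 49 windows, exact p = 0.525). Among the other words, GAGAGAGA was more common at summits (6.69% against 0.999%, adjusted exact p = 7.70e-30), as were the E-boxes CACGTG (2.42% against 1.11%, adjusted exact p = 0.000815) and CANNTG (33.3% against 29.6%, adjusted exact p = 0.00596). The GATA word TGATAA (2.998% against 9.65%, adjusted exact p = 1.85e-22) and the homeodomain word TAATTA (1.54% against 5.50%, adjusted exact p = 1.18e-14) were less common. Neither TGACTCA (29 against 24 windows, adjusted exact p = 0.649) nor the X-box (3 against 4, adjusted exact p = 1) differed. Both E-box calls were lost in the higher-signal 1301 peaks (adjusted exact p = 0.123 and 0.0748), and that of CANNTG also with the top peaks of replicate 1 alone (0.353). G and C made up 45.3% of summit windows and 35.3% of flanks, and RTAAAYA had a higher ratio than 67% of 200 reorderings of its own letters. The other words, the E-boxes among them, were not compared with reorderings of their letters. Their differences between summits and flanks were therefore not separated from base composition.

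**Figure D3:**
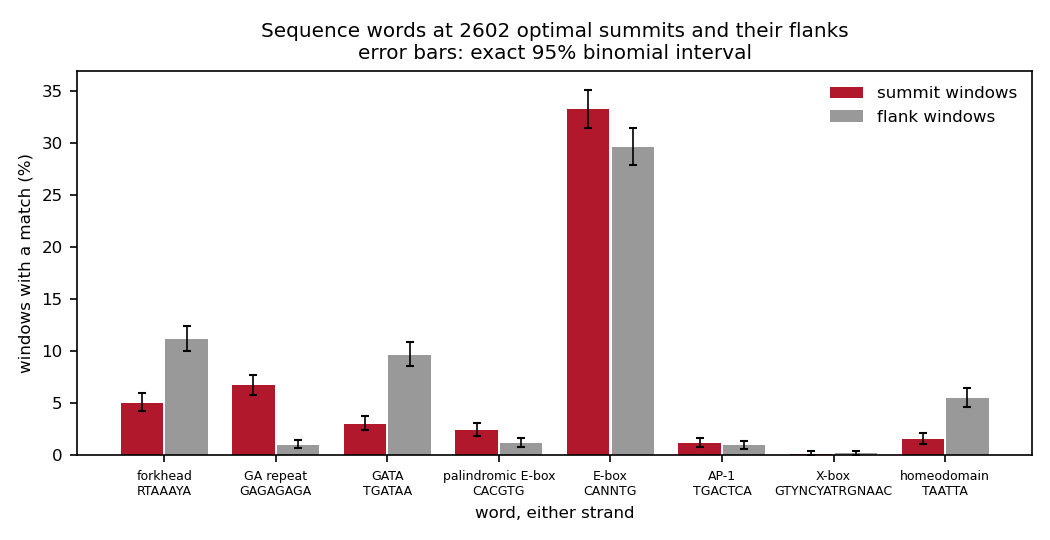
Share of windows (percent) with each of 8 words at 2602 optimal summits (red) and in their flanks (grey), on either strand. Bars start at 0 and error bars are exact 95% binomial intervals; RTAAAYA was found at 5.03% of summits and 11.1% of flanks.

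The loci of the transgene and its marker differed in peak density. Within 20000 bp of fkh-10 (chromosome I, 10163475 to 10165132, minus strand) there were 0 optimal peaks, 1 pooled peak with a signal of 15.5, 1 peak of replicate 1 and 0 of replicate 2. The median over protein-coding genes was 8 pooled peaks, and 2.06% of genes had as few as fkh-10. For the replicate lists this share was 0.461% and 0.396%. In the optimal set 45.4% of genes had 0 peaks at this distance, so that list cannot show a low count. Around unc-119 (chromosome III, 10902641 to 10908935) there were 10 pooled peaks, as many as or more than at 74.5% of genes, with 12 in replicate 1 and 23 in replicate 2. Its optimal peak (10903158 to 10903533, signal 60.9; replicates 34.4 and 27.5) lay in an unc-119 intron, 705 bp from the gene start.

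**Figure D4:**
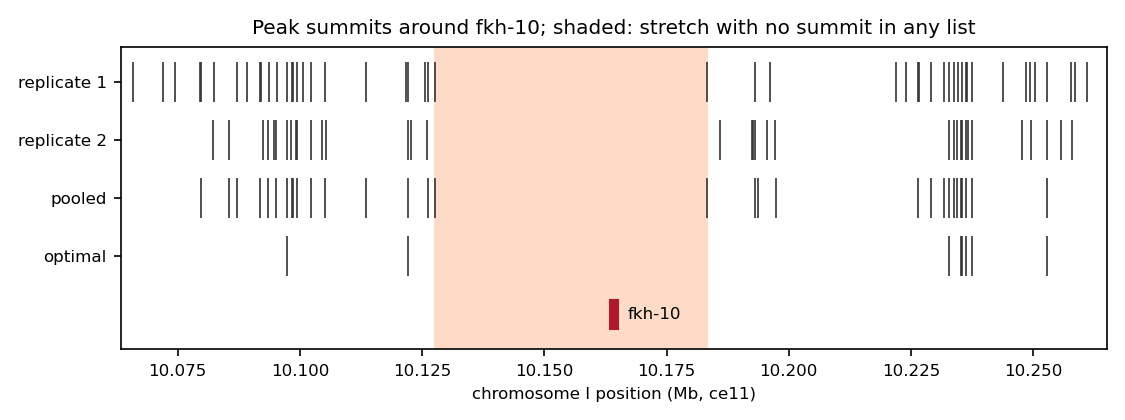
Positions of peak summits (vertical lines, chromosome I in Mb, ce11) around fkh-10 in the 2 replicate lists, the pooled list and the optimal set. The shaded stretch from 10127699 to 10183345 holds fkh-10 and no summit of any list.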

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

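Of these settings, the correlation outside the optimal set and the nearest-start assignment without peaks near fkh-10 and unc-119 were chosen after the data were seen. The promoter excess, the X excess and the replicate overlap against chance kept their direction and side of the threshold under the alternatives run for them, and the numbers of gene lists and RNA classes called stayed within 1.5 times. With either replicate left out, 36.3 to 39.2% of summits lay in promoters, the X ratio was 1.39 to 1.455 and the RTAAAYA ratio 0.516 to 0.528. Replicate overlap, support and correlation need both replicates, so none was left out there. Read depth is unknown, so its effect could not be examined, and the cause of the changes below was not tested except where the peak number sets them. The share of optimal peaks in both replicates was 65.6% with reciprocal overlap, 68.1% with summits within 100 bp, 38.05% with 1301 top peaks, 93.5% with 5204 and 99.6% with all peaks. Spearman's rho was 0.767 and 0.650 for pairing within 50 and 200 bp, 0.622 for peaks in the optimal set and 0.208 for those outside it. The higher-signal 1301 peaks left 3 other words called. The forkhead ratio was 0.859 for TGTTTAC. The share of genes with as few peaks as fkh-10 was 15.1% within 5000 bp in the pooled list and 45.4% in the optimal set.

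Directions turned for results that were not called in the main setting. Ratios of summit to flank counts for the AP-1 word were 0.926 in the higher-signal peaks and from 0.709 to 0.922 with either replicate left out, and those of the X-box from 0.692 to 2.2. Odds ratios in the higher-signal peaks were 1.49 for neurotransmitter, 0 for muscle, 1.65 for excretory and 0.959 for tRNA synthetase genes. With either replicate left out they ranged from 0.861 to 1.49 for muscle, from 0.947 to 1.65 for tRNA synthetase and from 0.454 to 1.06 for histone genes. In peaks of both replicates they were 1.03 for homeobox and 1.03 for neurotransmitter, 0.605 for muscle, 1.14 for excretory and 0.664 for tRNA synthetase genes. With the short promoter window they were 1.08 for excretory and 1.15 for histone genes, and with the long one 2.40 for neurotransmitter genes. With nearest gene starts they were 3.50 for neurotransmitter (adjusted exact p = 0.0379), 1.17 for neuropeptide, 1.03 for glia and 0.582 for tRNA synthetase genes. Of the other results for single lists, words and RNA classes under alternatives, 338 were the same, 14 lost and 5 gained a call.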

Other observations

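All tests of this part were chosen after the data were seen, with these exceptions: the comparison of RTAAAYA with reordered words at all optimal summits and the assignment to nearest gene starts. The recruitment element was picked after the positions of the X peaks and the enriched 6-base words were seen, but before its matches were counted. The summit sequences of the 20 highest peaks were part of the earlier results, and several hold near matches to the element. Matches among these 20 peaks therefore cannot be taken as independent of that choice. The reordering tests of the element were chosen after the 16 matches.

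Giving each summit to the nearest gene start raised the share of some gene lists and lowered that of others. By that assignment 25 of 28 pan-neuronal genes (89.3%, exact interval 71.8 to 97.7%) had an optimal peak, against 10.2% of other genes (Fisher's exact test, adjusted p = 7.08e-21). One of them was unc-119, the transformation marker, and without the peaks near fkh-10 and unc-119 the count was 24 of 28 (85.7%, adjusted exact p = 3.89e-19). Ribosomal protein genes fell from 57 to 32 of 83 (odds ratio 33.6 to 5.56), spliceosome genes from 18 to 12 of 47 (9.22 to 3.01), chaperone genes from 16 to 10 of 42 (9.13 to 2.74) and translation factor genes from 14 to 10 of 39, and all 4 lists stayed called higher. The summits of pan-neuronal genes outside the promoter window included those 4559 bp upstream of unc-10, 4679 bp upstream of unc-13, 1139 bp upstream of egl-3 and 1309 bp upstream of unc-64, with signals of 157, 116, 165 and 114; these 4 genes act in synaptic transmission or neuropeptide processing and were picked after their values were seen. Insulin and dauer signalling genes had a peak at 13 of 32 by this assignment (40.6%, adjusted exact p = 4.63e-05), against 5 of 32 by promoter window. Hedgehog-related genes had 0 of 59 (adjusted exact p = 0.0121). Longer upstream sequence gives a gene more summits by nearest start, and this was not corrected for.

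Of 18 annotated genes for SL2-type spliced leader RNAs, which are joined to messages of downstream operon genes, 6 had an optimal summit within 500 bp and the others had none: sls-2.4 (signal 315), sls-2.1 (303), sls-2.2 (273), sls-2.3 (172), sls-2.6 (111.6) and sls-2.8 (84.8). The summit counted for sls-2.3 (chromosome II, 5543753) lay closer to sls-2.2 (5543598 to 5543707) than to sls-2.3 (5544164 to 5544273). That gene was thus counted through a summit beside its neighbour. The 6 genes were among the 14 snRNA genes near a summit. None of 12 annotated SL1 RNA genes had one, a difference that did not pass the test (Fisher's exact p = 0.0568). Whether short reads can be placed uniquely at the SL1 RNA and rRNA genes was not tested, so their lack of summits cannot be read as a lack of binding. The summit assigned to the egg-5 promoter lies at 4172173 on chromosome I, beside sls-2.4 (4172206 to 4172315), and the H41C03.3 summit at 5844796 on chromosome II lies beside sls-2.1 (5844865 to 5844974).

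In a scan of 2080 words of 6 bases, 676 were more common at summits and 524 in the flanks (exact McNemar tests, adjusted). The lowest p among the higher words was that of GAGAGA (25.7% of summits against 6.50% of flanks), and CGTCTC (15.6% against 2.92%), GACGCA (12.2% against 1.96%) and ACGCAG (12.2% against 2.11%) followed among others. A and T made up 34.4% of the letters of the higher words and 71.4% of the lower ones.

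The few forkhead words at the summits were weighed first. If base composition gave the pattern, words of the same letters would be as rare, and 67% of 200 reorderings of RTAAAYA had a lower ratio than RTAAAYA itself, so its rarity is consistent with the low A and T content of these summits. If promoter signal of broadly expressed genes hid sites bound through the word, RTAAAYA would be enriched at peaks outside promoters. By the rule first written, a ratio below 1 there with an exact McNemar p under 0.05 spoke against hidden sites. The ratio was 0.493 (82 against 167 of 1602 windows, bootstrap interval 0.380 to 0.632, exact McNemar p = 4.02e-08), which met that rule. The rule was then replaced, because a ratio below 1 decides nothing where the reorderings have a median of 0.410. Under the later rule RTAAAYA would stand above nearly all of its reorderings at these peaks. Of the reorderings, 77% were lower than RTAAAYA, so hidden sites cannot be told apart from base composition. Whether FKH-10 reached these sites without its own word or whether the signal is not specific to FKH-10 stays open, since the control library and other factors were not analysed here.

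The strongest peaks lie mostly on X outside promoters of protein-coding genes, and more such sequence on X was weighed as a cause. Over all optimal peaks outside promoters it is argued against as the whole cause. X held 450 of these 1602 peaks, 1.52 times the share expected from such sequence (exact interval 1.40 to 1.64). In promoter windows X held 194 of 1000 peaks, 1.34 times the expected share (exact interval 1.17 to 1.52). The X excess was thus not confined to sequence outside promoters, and this ratio was not computed for the strongest peaks alone. The recruitment element of the X dosage compensation complex, GCGCAGGGAG with at most 2 mismatches, was within 50 bp of 16 of 58 X summits among the 200 highest peaks. It was in 2 of their flanks, a ratio of 6.60 (Fisher's exact p = 0.000513, a test that leaves out the pairing of each flank with its summit). Of 200 reorderings of the element, 0.5% matched as many X summits. Of the matches, 11 were among the 14 X summits of the 20 highest peaks (8 with at most 1 mismatch), which 0 reorderings reached in either case. The sequences of these 20 peaks were available when the element was picked, so these shares are no independent test against base composition. For the other 44 X summits, 37% of reorderings matched as many as the element did, so there base composition stays open. The match was not confined to X: 17 of 142 autosomal summits of that group had it (11.97%, X against autosomes exact p = 0.0110), as did 9.90% of X and 9.80% of autosomal summits outside the group; with at most 1 mismatch it was at 9 X and 0 autosomal summits among the 200 and at 11 X and 15 autosomal summits outside. Over all X summits it was more frequent in promoters than outside them with at most 2 mismatches (17.01% and 9.11%, exact p = 0.00665), and the order was the opposite with at most 1 (1.55% and 3.78%, exact p = 0.214). Signal at recruitment sites of that complex is therefore a candidate explanation for some of the strongest X peaks, and with 1 group no comparison of groups could test a biological one.

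The gap in peaks around fkh-10 runs over 55646 bp with no summit in any list and has length rank 4 among such gaps on the chromosomes analysed, with rank 4 in each replicate list and rank 11 in the pooled list. Sequence that short reads cannot place is argued against: 91.6% of its 31-base words occur once in the genome, and 38.3% of 1000 random windows of that length had a smaller share. Gaps of the pooled list at least as long hold a share of 0.00836 of protein-coding genes. If the control carried extra transgene copies, they could raise the control there and remove peaks. The immunoprecipitated animals carried the transgene too, so copies could raise both libraries. Around the marker gene unc-119 there were 10 pooled peaks within 20000 bp, as many as or more than at 74.5% of genes. Without the control signal, extra copies in the control cannot be told apart from a lack of binding at fkh-10. Longer gaps without fkh-10 also exist, the longest of 219568 bp on chromosome V (2344635 to 2564203).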
